A study of Homo sapiens with 6 samples.

How the data were processed

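RNA-seq was made from 6 Jurkat libraries, 3 with an empty vector (EV) and 3 with stable SCML4 overexpression. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a SMARTer mRNA-seq kit. FastQC, STAR and SAMtools and the genome build hg19 are named, per the submitters' processing notes, without versions. The counting tool, the gene annotation and the source of the gene lengths are not given in the sources used here. The deposited table holds FPKM, reads scaled by gene length and by the reads of the library, with 1 column per library, per the file headers. It has 39012 genes named by symbol, of which 15115 are at 0 in every library. Groups and replicate numbers were taken from the sample titles.

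FPKM values of a gene are whole multiples of what 1 read is worth. From these steps the number of reads behind each value and the total of each library were worked out. Of the 23897 genes above 0, 99.992% came out as whole reads in all libraries within a tolerance of 0.002 of a read, widened slightly for large counts. A common divisor of a gene's counts cannot be seen this way. In simulated data of 12000 genes, 98.95% of genes with 10 or more reads were recovered exactly. Library totals were 9631850, 8968067 and 9680394 reads in EV and 9064152, 10336597 and 8953671 in SCML4. Between 99.63% and 99.64% of each total lay on the genes of the table, and mitochondrially encoded genes took 5.59% to 6.23%. A count of 0 allows up to 3 reads, or 0.29 to 0.335 CPM by library. Floors and the interval of the pooled SCML4 ratio cover counting error only, since no molecular identifiers are described. Intervals of log2 differences come from the spread between libraries.

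The gene length implied by the FPKM of each gene was compared with GENCODE 29 on GRCh38, which was used for lengths, GC content and gene order and not for coordinates, since the build differs. The implied lengths are not those of the named genes. Against 5 definitions of a gene's own length the highest Spearman correlation over 13614 genes was 0.014. For SCML4 the implied length was 22347 bases against an exonic length of 7116. FPKM levels are therefore not compared between genes, and levels are given as CPM, reads per 1000000 of the library total. A ratio between libraries of one gene does not depend on the length. The pseudocount and the filter on FPKM do, so that TNF fell below the filter. The p-values of the test described next also depend on the length. That test fits the variance of genes against their mean level, here in FPKM.

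The comparison, fixed before the data were examined, was SCML4 minus EV on log2(FPKM + 1) by limma-trend, version 3.58.1 in R 4.3.3, for genes with a mean FPKM of at least 0.5 over the 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. It left 15357 genes. Fold changes are on the log2(FPKM + 1) scale unless the fit of reads is named. No duplicate libraries were found, the chi-square per gene within a group being 2.71 to 12.2. Replicate numbers were not used to pair libraries. In all, 40 gene lists (31 for the study's themes and 9 controls) were fixed beforehand. Camera in limma, with a preset correlation of 0.01 between genes, tested the 35 lists with at least 5 genes above the filter. Adjusted p values of lists are over these 35.

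The genes named were fixed by rule. They were SCML4, up to 12 genes in each direction among those past the threshold with groups apart and at least 2 FPKM in the higher group, and from each list up to 4 genes of smallest unadjusted p (1 for control lists). No gene met the second part. Any gene named outside the rule is said to have been chosen after its values were seen. Some genes that the rule or a fit would name are not reported here.

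Alternatives fixed beforehand were other pseudocounts, filters, scalings, prior settings, library weights, a replicate block, stricter thresholds, other list tests and leaving out each library. Added after the data had been seen were fits of the recovered reads (genes with a mean of at least 10 reads): limma-voom with and without library weights, limma-trend on log2(CPM + 1), limma-voom without EV replicate 1, and limma-trend after correcting each library for GC content and exonic length with lowess, span 0.3. GC content and length were known for 94.26% of those genes. The tests were tried on simulated data, with the changed genes picked among those with a mean of at least 50 reads. All of them were changed in the same simulation, which makes adjusted p values easier to pass than where few genes change. With 15319 genes simulated from the means and spreads of these libraries, limma-trend found 26 of 67 genes changed 1.5-fold, 47 of 67 changed 2-fold and 63 of 66 changed 4-fold, and called 13 unchanged genes. The weighted fit of reads, on 14153 genes, found 38 of 67, 57 of 67 and 66 of 66, and called 7 unchanged genes. Camera called 5% of 200 unchanged lists at an unadjusted p under 0.05. Genes were simulated independently of each other, so this rate does not cover lists whose genes correlate. Recovery of reads and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.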

Results

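Transcript levels were measured by RNA-seq in Jurkat cells, an established human line derived from a T cell acute lymphoblastic leukaemia. One group of 3 libraries came from cells carrying an empty vector (EV). The other group of 3 came from cells that stably overexpressed SCML4, a protein of the Scm-like Polycomb family. The labels state that all 6 cultures had been stimulated for 6 h with PMA at 100 ng/ml and ionomycin at 1 µM, a pair of compounds that activates protein kinase C and raises calcium and so bypasses the T cell receptor. Libraries held between 8953671 and 10336597 reads, recovered from the deposited FPKM values. Levels are given as reads per 1000000 reads of the library (CPM). The series as a whole concerns SCML4 in CD8 T cells that reside in tumours, with fatty acids, killing function and chromatin as its themes. The comparison asks which transcripts differ when SCML4 is present in excess. It cannot tell this excess apart from any other difference between the EV and SCML4 cells. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

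SCML4 itself was nearly absent from the EV libraries and abundant in the SCML4 libraries. The EV libraries held 7, 2 and 1 reads from the gene and the SCML4 libraries 570, 657 and 506. This corresponds to 0.351 ± 0.331 CPM in EV and 61.0 ± 3.89 in SCML4 (mean ± SD, n = 3 each). Pooled over each group the ratio was 173, with a 95% exact counting interval of 93.8 to 361 that covers counting error only. Of the 10 reads in EV, 7 came from EV replicate 1, so the ratio rests largely on that library. The deposited FPKM were 0.0325, 0.00998 and 0.00462 in EV and 2.81, 2.84 and 2.53 in SCML4. These FPKM rest on an implied length of 22347 bases against an exonic length of 7116, which lowers them. On the log2(FPKM + 1) scale, which understates the change of a gene with low FPKM, the difference was 1.88 with an SE of 0.13 and a 95% interval of 1.56 to 2.19. This was the smallest p of all genes tested, with an adjusted p of 0.0619 in limma-trend, and it did not pass 0.05. In a limma-voom fit of the recovered reads the adjusted p was 1.47e-06, and over all alternatives it ranged from 2.89e-11 to 0.982. An exact two-sided permutation test of 3 against 3 libraries gave p = 0.1, the smallest value that design allows.

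**Figure D1:**
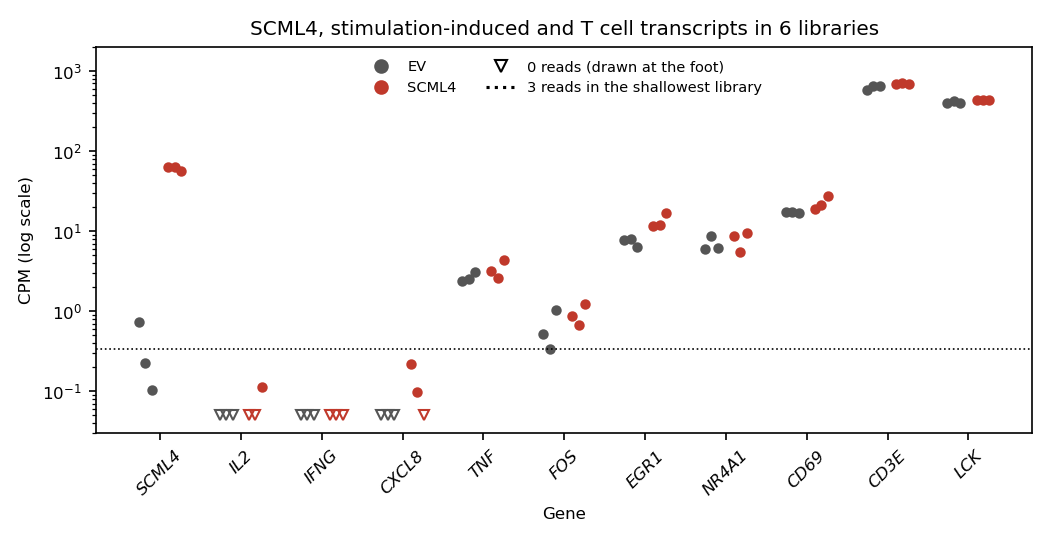
CPM on a log axis for SCML4, 8 transcripts that T cell stimulation is known to induce and a pair of T cell transcripts, with 1 point per library (EV grey, SCML4 red) and open triangles for 0 reads. SCML4 lies at 0.351 CPM on average in EV and 61.0 in SCML4, while IL2, IFNG and CXCL8 lie at or near 0 reads in all 6 libraries.

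No transcript, SCML4 included, passed the threshold in the FPKM comparison. Its p-values rest on an intensity trend in FPKM, whose lengths are not those of the genes. With that trend left out 4 genes passed, SCML4 among them. Of 15357 genes tested by limma-trend, 0 reached an adjusted p under 0.05, and after SCML4 the next smallest adjusted p was 0.467. At an unadjusted p under 0.05 there were 781 genes, or 5.09%, where chance alone gives about 5%. With library weights, which were estimated from these same libraries, there were 1249 in limma-trend, and 1202 of 14156 in the weighted limma-voom fit of reads. Without weights the limma-voom fit of reads had 746, or 5.27%. In 1735 genes (11.3%) the 3 values of one group all lay above the 3 of the other, against the 10% that chance gives, with SCML4 higher in 925 and lower in 810. The median fold change of all genes was 0.01 in log2. Among genes with at least 50 reads on average, the 95% interval of a fold change reached a median of 0.26 in log2 to either side of the estimate. In simulated data of this design, changes were set only in genes with at least 50 reads on average. There the test found 38.8% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 95.5% of those changed 4-fold. Genes with fewer reads were not covered. The simulated genes were all changed together, and 13 unchanged genes were called beside them. Benjamini-Hochberg adjustment is easier to pass when many genes change, so these rates do not hold where few genes change. In the real data SCML4, with a pooled ratio of 173, had an adjusted p of 0.0619 in limma-trend.

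**Figure D2:**
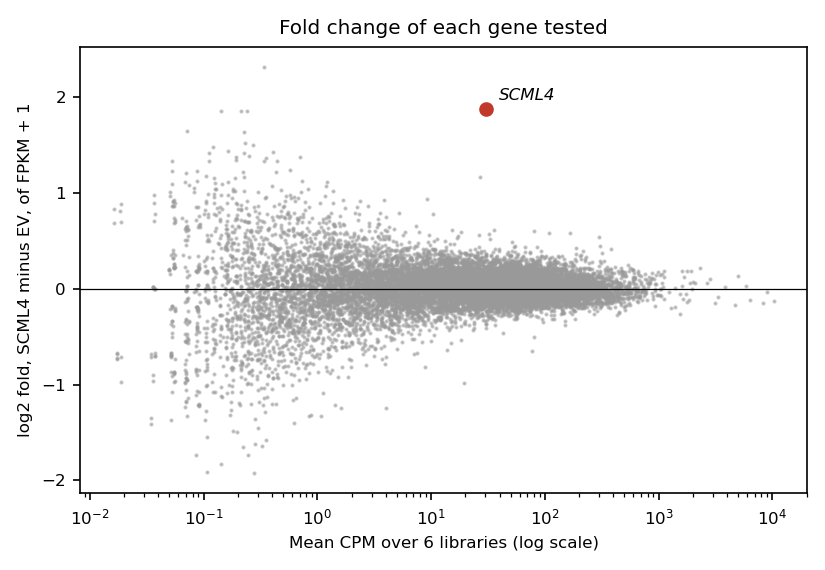
Difference between SCML4 and EV on the log2(FPKM + 1) scale (vertical axis) against mean CPM over 6 libraries (horizontal log axis) for the 15357 genes tested, 1 point per gene. SCML4, in red, lies at 1.88, apart from genes with as many reads.

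A fit of the recovered reads that gave each library its own weight, chosen after the data had been seen, called 14 of 14156 genes, 11 higher and 3 lower with SCML4. Apart from SCML4, the genes named from this fit were chosen because they were called, after their values had been seen. CHI3L2, a chitinase-like secreted protein, stood at 133 ± 12.1 CPM in EV and 200 ± 13.1 in SCML4 (mean ± SD), a log2 difference of 0.63. Its adjusted p was 0.000172 in this limma-voom fit, 0.0643 without weights and 0.537 in limma-trend on FPKM. CEBPE, a transcription factor of granulocyte maturation, stood at 16.1 ± 2.81 and 37.2 ± 8.42 CPM, a log2 difference of 1.15. KCNH2, a voltage-gated potassium channel, stood at 86.4 ± 4.50 and 130 ± 13.8. The retinaldehyde dehydrogenase gene ALDH1A2, the epoxide hydrolase gene EPHX2, the microRNA host gene MIR223HG and the ribosomal protein genes RPL8, RPL38 and RPLP1 were also higher, by 0.42 to 1.13 in log2. In ALDH1A2 the values of the groups overlapped. Lower with SCML4 were CCR9, a chemokine receptor of thymic and gut T cells, at 26.2 ± 6.25 CPM in EV and 12.7 ± 2.04 in SCML4, MAGEA4, a cancer-testis antigen, at 5.88 ± 1.92 and 2.21 ± 0.179, and CFTR, a chloride channel with 2 to 18 reads per library. The same weighted fit called 35 genes when EV replicate 1 was grouped with SCML4 replicates 1 and 2. Without library weights, SCML4 was the single gene called by limma-voom. With correction for GC content and transcript length, SCML4, CHI3L2 and CEBPE were called. The weights set EV replicate 1 at 0.313 against 0.811 to 1.80 for the other 5 libraries, and without that library limma-voom called 13 genes, 10 of them among the 14.

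EV replicate 1 stood apart from the other 5 libraries. On the first principal component, with 26.5% of the variance, it lay at -38.6 and the others between 0.35 and 11.6. Its counts differed from those of the other EV replicates by a chi-square per gene of 12.2 in both pairs, against 2.71 for EV replicates 2 and 3 and 3.34 to 6.10 between SCML4 libraries. Across 13343 genes, which are not independent replicates, the deviation of EV replicate 1 from the mean of 6 libraries correlated with GC content at a Spearman coefficient of -0.50. The other libraries lay between 0.05 and 0.29, and the difference between SCML4 and EV at 0.33.

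**Figure D3:**
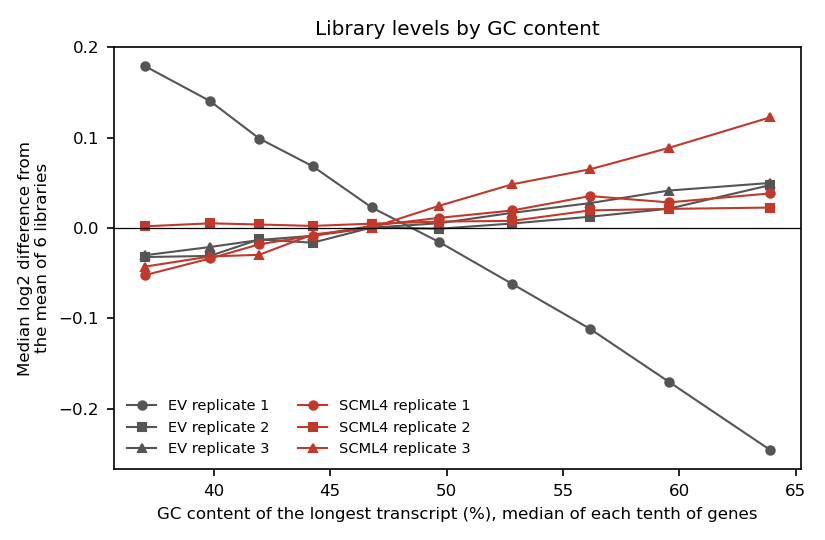
Median log2 difference of each library from the mean of 6 libraries (vertical axis) in 10 equal bins of genes ordered by the GC content of the longest transcript in percent (horizontal axis), EV in grey and SCML4 in red, with the marker shape giving the replicate. EV replicate 1 runs from 0.18 in the genes of lowest GC content to -0.25 in those of highest.

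Of the transcripts that PMA and ionomycin are known to induce in T cells, several cytokines were at or near 0 reads in both groups, while others were detected in every library. IL2, the T cell growth factor, had 1 read in SCML4 replicate 3 and 0 in the other 5 libraries, and IFNG had 0 in all 6. A count of 0 allows up to 0.335 CPM (3 reads) in the shallowest library. CXCL8 had 3 reads over all libraries and CSF2 had 1. TNF stood at 2.68 ± 0.37 CPM in EV and 3.39 ± 0.887 in SCML4 (mean ± SD), and FOS at 0.629 ± 0.362 and 0.929 ± 0.279. CD69 had 155 to 249 reads per library and NR4A1 57 to 84. Apart from CD69 and NR4A1, these genes were picked after their values had been seen. Of the 28 cytokine and chemokine genes listed, 10 had 0 reads in every library and 6 had a mean above 1 CPM. None of the 8 tested passed, and the list gave an adjusted p of 0.718 in limma's camera test. The smallest unadjusted p values of that list were those of TGFB1, with a log2 difference of 0.29, and LTB, with 0.33.

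Immediate early genes gave 0 calls among 19 tested over all genes and 1 when adjusted over the list alone. That gene was EGR1, an early growth response transcription factor, at 7.33 ± 0.814 CPM in EV and 13.4 ± 2.84 in SCML4, with a log2 difference of 0.78 and an adjusted p of 0.905 over all genes in limma-trend. Of the 19 genes 14 had positive differences, and the list had an adjusted camera p of 0.167, or 0.0211 with a mean FPKM of at least 5. With an estimated correlation and the main filter the adjusted camera p was 0.686. JUN had a difference of -0.21, BTG2 of 0.22 and ATF3 of 0.31. The feedback regulators of MAP kinase signalling, a list of phosphatases and Sprouty-family inhibitors, were called higher as a group. Of 17 tested, 14 had positive differences, with a mean of 0.12 in log2 and an adjusted camera p of 0.0485, which became an adjusted p of 0.686 with an estimated correlation. None of its genes passed singly, DUSP1 having a difference of 0.18 and SPRED2 of 0.16. The call was lost without EV replicate 2, EV replicate 3, SCML4 replicate 1 or SCML4 replicate 3, at adjusted p values of 0.13, 0.194, 0.0878 and 0.195. It was also lost with a pseudocount of 0.1 (0.0524) or 0.5 (0.05004), under quantile normalization (0.0602) and with library weights (0.08). Targets of NF-κB (18 tested, 13 positive) and of NFAT and calcineurin (19 tested, 14 positive) had adjusted camera p values of 0.169 and 0.386. After correction of the reads for GC content and length that of the NF-κB targets was 0.0238, and with an estimated correlation 0.686. In those lists REL had a difference of -0.25, TNFAIP3 of 0.25 and ORAI2 of 0.16.

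T cell effector and surface genes gave 0 calls in limma-trend. Of 17 cytotoxic effector genes tested, 10 had positive and 7 negative differences, with an adjusted camera p of 0.996; the median was positive at 0.06, the mean negative at -0.05 and the test pointed up. PRF1, which encodes perforin, stood at 7.77 ± 1.85 CPM in EV and 5.81 ± 1.42 in SCML4, and KLRD1 at 2.30 ± 0.854 and 0.952 ± 0.762. Among 12 costimulatory and activation receptors (adjusted p = 0.996), CD69, an early activation antigen, stood at 17.2 ± 0.215 and 22.6 ± 4.59, and TFRC, the transferrin receptor, at 484 ± 11.3 and 413 ± 62.8. That list's mean was positive while its test pointed down. In the T cell receptor complex and its proximal signalling, 19 of 25 differences were positive (adjusted p = 0.257), with CD3E at 0.16, CD3D at 0.15 and THEMIS at -0.24. Inhibitory receptors (15 tested, 10 positive, adjusted p = 0.421), tissue residency genes (10 tested, 5 positive, adjusted p = 0.996) and genes of lymph node homing and egress (12 tested, 2 positive, adjusted p = 0.386) were likewise not called, the last being called without EV replicate 1 (0.0179). On reads camera also called the lymph node homing list in the weighted fit (0.0334) and without EV replicate 1 (0.000875). With an estimated correlation over all 6 libraries that list had an adjusted camera p of 0.837. CD160 had a difference of -0.29, where the inhibitory receptors tested had a median of 0.11 and a mean of 0.19. That mean includes BTLA at 1.37 and LAYN at 0.82, which had 0 to 6 and 3 to 12 reads per library. ITGAE, the integrin that binds E-cadherin, had one of -0.28, and CCR7, the lymph node homing receptor, one of -0.61. T cell transcription factors (25 tested, 16 positive) had an adjusted camera p of 0.996, with IKZF3 at -0.40 and BCL11B at -0.15. The oncogene programme of T cell leukaemia (16 tested, 10 positive) had an adjusted p of 0.452, with LYL1 at 0.33.

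The lists of chromatin genes were not called by camera. Among 36 components of the Polycomb repressive complexes, 18 had positive and 18 negative differences, with a median of -0.0016 in log2 and an adjusted camera p of 0.993. EZH2, the catalytic subunit that methylates histone H3, stood at 236 ± 29.8 CPM in EV and 208 ± 8.60 in SCML4, and CBX7 at 15.8 ± 1.46 and 18.1 ± 1.79. The 12 genes of the HBO1 acetyltransferase complex with BRPF and ING subunits divided into 5 positive and 7 negative (adjusted p = 0.996). KAT7, its catalytic subunit, stood at 79.5 ± 2.73 and 71.9 ± 2.00 CPM. Of 18 HOX and other developmental Polycomb targets tested, 12 had positive differences (adjusted p = 0.319), with HOXC6 at 0.66 and HOXA2 at -0.51 from means of at most 1.12 CPM.

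Metabolic genes gave 0 calls over all genes, and the genes of cholesterol synthesis were called higher as a group. All 22 tested had positive differences, with a mean of 0.15 in log2 and an adjusted camera p of 0.0019, which became an adjusted p of 0.686 with an estimated correlation. INSIG1, a sterol-regulated inhibitor of SREBP processing, stood at 274 ± 20.8 CPM in EV and 336 ± 47.0 in SCML4, and the mevalonate pathway gene MVD at 40.2 ± 4.52 and 47.3 ± 7.03. The call was lost without EV replicate 1 (mean 0.08, adjusted p = 0.235) and without SCML4 replicate 1 (adjusted p = 0.74). It was also lost with library weights (0.0677). Fatty acid synthesis and uptake genes (24 tested, 19 positive, adjusted p = 0.18) and fatty acid oxidation genes (25 tested, 12 positive, adjusted p = 0.996) were not called. PLIN3, a lipid droplet coat protein, had a difference of 0.33 and an adjusted p of 0.905 in limma-trend, and the acyl-CoA dehydrogenase ACADVL of 0.16. Glycolysis genes (23 tested, 15 positive) had an adjusted p of 0.515 in limma's camera test. Adjusted over the list alone, 1 of them passed, the aldolase gene ALDOC, at 6.05 ± 0.395 and 8.30 ± 0.354 CPM. The nuclear genes of oxidative phosphorylation (39 tested, 25 positive) had an adjusted p of 0.167, or 0.00414 without SCML4 replicate 3, and the mTOR pathway (34 tested, 23 positive) one of 0.452. In the weighted fit of reads camera also called the oxidative phosphorylation list (0.0334). With an estimated correlation over all 6 libraries that list had an adjusted camera p of 0.686.

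Genes of the cell cycle, of stress and of antigen presentation were not called by camera. The lists of the G1 and S phases (26 tested, 16 positive) and of the G2 and M phases (25 tested, 16 positive) had adjusted p values of 0.521 and 0.0557, with CCND2 at 0.64 and the mitotic kinase PLK1 at 0.24. The list of the G2 and M phases was called without EV replicate 1 (adjusted p = 0.000411) or SCML4 replicate 3 (0.044), without a filter (0.0133), after rescaling to TPM (0.0468) and with library weights (0.000653). On reads camera called it in the weighted fit (0.000832), without EV replicate 1 (0.0003685) and after correction for GC content and length (0.00852). With an estimated correlation over all 6 libraries its adjusted camera p was 0.686. Apoptosis genes (22 tested, 12 positive, adjusted p = 0.996) included the p53 target BBC3 at 0.65. Interferon response genes (27 tested, 18 positive) had an adjusted p of 0.663 and class I antigen presentation (17 tested, 13 positive) one of 0.257, with CALR at 0.22. The ATF4 stress response (21 tested, 14 positive, adjusted p = 0.664), the unfolded protein response (18 tested, 8 positive, adjusted p = 0.996), heat shock genes (15 tested, 6 positive, adjusted p = 0.664) and hypoxia targets (15 tested, 5 positive, adjusted p = 0.664) had mean differences between -0.02 and 0.03. PHGDH had a difference of 0.21, XBP1 of 0.26 and HSP90AA1 of -0.26. In the unfolded protein response the mean was positive at 0.01, the median negative and the test pointed down.

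Among control lists, ribosomal proteins were called higher and mitochondrially encoded transcripts lower with SCML4. Of 38 ribosomal protein genes 32 had positive differences, with a mean of 0.13 in log2 and an adjusted camera p of 0.0019. With an estimated correlation the adjusted p was 0.819. RPL13 stood at 186 ± 14.0 CPM in EV and 230 ± 8.94 in SCML4. These genes have many processed pseudogenes, with which reads can be shared. The call was lost without EV replicate 2 (adjusted p = 0.392), SCML4 replicate 1 (0.268) or SCML4 replicate 2 (0.142). Of 13 mitochondrially encoded transcripts 10 had negative differences, with a mean of -0.07 and an adjusted p of 0.0232, or an adjusted p of 0.686 with an estimated correlation. MT-ND4 stood at 8753 ± 640 and 7882 ± 187 CPM. This call was lost without EV replicate 2 (0.13), EV replicate 3 (0.134), SCML4 replicate 1 (0.0878) or SCML4 replicate 3 (0.0578). It was also lost without a filter on low values (0.242), under quantile normalization (0.314), without the intensity trend (0.102) and on log2(CPM + 1) of the reads (0.0631). Housekeeping genes (15 tested, adjusted p = 0.996) and replication histones (15 tested, adjusted p = 0.996) were not called. Markers of B cells, myeloid cells, natural killer cells, kidney epithelium and fibroblasts had 3, 3, 2, 2 and 4 genes above the filter and were not tested as lists. BLK had a difference of 0.47, AIF1 of 0.13, NCAM1 of 0.73, KRT8 of 0.38 and FN1 of -0.23, each with an adjusted p of at least 0.905 in limma-trend. The value of NCAM1 rests on 0 to 4 reads per library. In the HBO1, Polycomb, fatty acid oxidation and housekeeping lists the median and the mean differed in sign, and camera pointed up in the HBO1 list and down in the other 3. Over all lists, 704 list entries were tested and 0 passed.

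**Figure D4:**
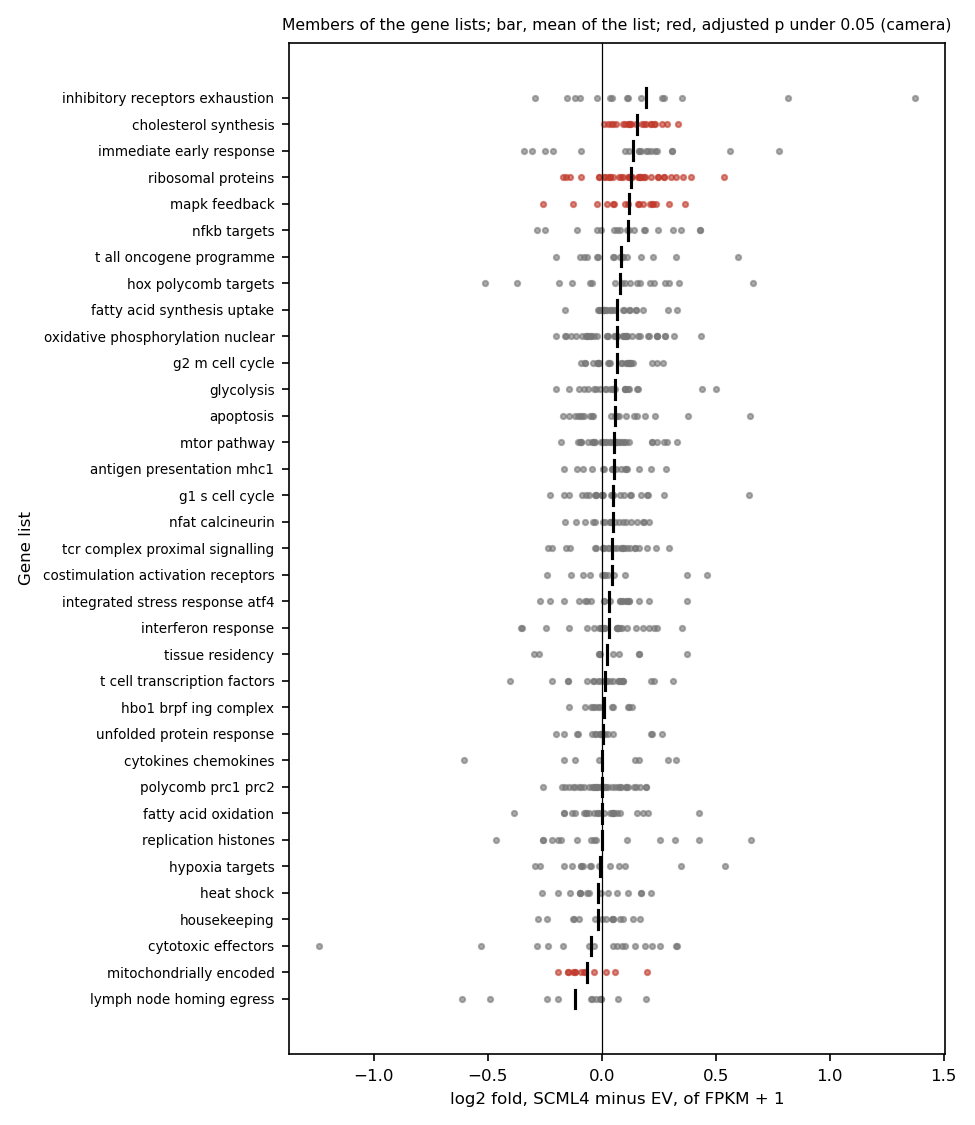
Differences between SCML4 and EV on the log2(FPKM + 1) scale (horizontal axis) for the tested genes of 35 lists (vertical axis), 1 point per gene, with a black bar at each list's mean and lists with an adjusted camera p under 0.05 in red. The means of all 35 lists lie between -0.12 and 0.19, and 4 lists are red.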

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

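The fits of reads and the GC correction were chosen after the data had been seen; the other settings were fixed beforehand. The number of genes changed stayed at 0 with pseudocounts of 0.1 and 0.5, the stricter filter, rescaling to TPM, median of ratios, quantile normalization, the robust prior, both stricter thresholds and each library left out (0 to 0). Without a filter it was 7 (5 higher, 2 lower), without the intensity trend 4 (3 higher, 1 lower), and with library weights 1 (1 higher). With reads it was 1 in limma-voom (1 higher), 14 with library weights (11 higher, 3 lower), 1 on log2(CPM + 1) (1 higher), 13 without EV replicate 1 (9 higher, 4 lower) and 3 after correction for GC content and length (3 higher). The causes were not tested. Members of gene lists that changed numbered 2 in the weighted fit and 2 without EV replicate 1, both on reads, and 0 elsewhere.

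The SCML4 transcript passed the threshold at 1.88 without a filter (adjusted p = 0.00871) and without the trend (0.00353), at 1.90 with library weights (0.0301), and on reads at 7.56, 7.99 with weights, 5.54 on log2(CPM + 1), 8.20 without EV replicate 1 and 7.55 after the GC and length correction. On reads the scale has a smaller pseudocount relative to the level, which makes the difference larger. It did not pass with a pseudocount of 0.1 (4.62, adjusted p = 0.253) or 0.5 (2.65, 0.074), after rescaling to TPM (1.19, 0.0633), median of ratios (1.87, 0.0639) or quantile normalization (1.82, 0.112), or with the robust prior (1.88, 0.071). Leaving out 1 library at a time gave 1.85 to 1.92, with adjusted p values of 0.15 to 0.54. With a mean FPKM of at least 5 the gene is not tested, so that filter gives no value. Intervals were wider in genes with fewer reads. The 95% intervals of log2(FPKM + 1) reached a median of 0.26 to either side in 11373 genes with a mean of 50 or more reads and 0.63 in 3984 genes under 50.

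Of the 35 lists, 4 were called. Quantile normalization called 2, the stricter filter 5, TPM 5, the weighted fit of reads 7, the GC and length correction 6, an estimated correlation 0 (1 list at an unadjusted p under 0.05) and fry 0 (4 lists at an unadjusted p under 0.05). Leaving out 1 library at a time called 0 to 5. Over all settings the adjusted p of ribosomal proteins ranged from 2.78e-18 to 0.819, of cholesterol synthesis from 1.60e-07 to 0.74, of mitochondrially encoded transcripts from 0.00135 to 0.686 and of MAP kinase feedback from 0.0115 to 0.686. Lists gained were those of the G2 and M phases, immediate early genes, lymph node homing, oxidative phosphorylation and NF-κB targets, each under some settings. With a pseudocount of 0.1 or 0.5 the MAP kinase feedback list was lost (adjusted p = 0.0524 and 0.05004). Leaving SCML4 out of lists was not run, since no list holds it.

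The shared replicate numbers do not pair the libraries: residuals of same-numbered libraries correlated at -0.02, -0.05 and -0.01. With a replicate block 0 genes and 3 lists were called, MAP kinase feedback being lost (adjusted p = 0.0751), the SCML4 difference was 1.88 (adjusted p = 0.982), and no sample correlated best with its own number.

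Among 130 genes followed through the settings, 2802 single-gene values kept their direction and side of the threshold and 10 changed sign. LTA was -0.0018 with library weights, -0.077 to 0.35 with 1 library left out and -0.11 on reads without EV replicate 1. NR4A1 was -0.091 with library weights and -0.067 in the weighted fit of reads. CD27 was -0.043 to 0.80 and JADE2 -0.017 to 0.20 with 1 library left out, and -0.0345 and -0.0186 on reads without EV replicate 1. IL16 was -0.052 to 0.27 with 1 library left out. The cause was not tested.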

Other observations

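Tests of the stimulation transcripts and of the gene lengths, the fit of reads and the GC correction were chosen after the patterns had been seen. Both groups carried a transcriptome of a T cell leukaemia line. Mean reads per library were 8761 for RUNX1, 4585 for TAL1, 3690 for BCL11B, 3524 for MYB and 1658 for GATA3, transcription factors of T cell leukaemia. Among T cell receptor components and kinases, CD3E had 6258 reads, ZAP70 5815 and LCK 3986.

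Of the transcripts that stimulation with PMA and ionomycin is known to induce, IL2 had 1 read in 6 libraries and IFNG 0, while CD69 had 155 to 249 reads per library and NR4A1 57 to 84. Gene names set on the wrong rows are argued against: 15 T cell and T cell leukaemia genes lay at a median percentile of 98.2 among rows with reads. A candidate explanation is that the cells were lysed outside the window of stimulation or were not stimulated as labelled. Of the cytokine and chemokine list 6 of 28 genes exceeded a mean of 1 CPM, but with no unstimulated library this cannot be told apart from a low response of the line. No biological explanation was tested, since all 6 libraries carry the same treatment label.

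The lengths behind the FPKM are not those of the genes. A different definition of the gene's own length is argued against by the highest of 5 Spearman correlations, 0.014. A candidate explanation is that a column of lengths in the order of Ensembl identifiers was set beside rows in reverse order of gene names. Of 120 rows with a length among the first 200, 59 had a length within 0.5% of a gene within 3 places of the same position in that order, where 100 shuffles gave at most 8. Position by position, with no shift allowed, the Spearman correlation with that order was 0.113 over those 120 rows, -0.0048 over the first 644 rows with a length and 0.502 over all 12917 of them. Levels of different genes cannot be compared by these FPKM. The fold of one gene between libraries is left as it was apart from the pseudocount and the filter. The intensity trend behind the p-values of limma-trend also rests on these FPKM.

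The lists of ribosomal proteins, cholesterol synthesis, mitochondrially encoded transcripts and MAP kinase feedback were called by camera, each by at most 0.15 in mean difference of log2(FPKM + 1). The trend with GC content and length as the whole cause is argued against by the mean log2 differences. After correction of the reads these were 0.103, 0.138, -0.0849 and 0.15, against 0.135, 0.163, -0.0647 and 0.175 before it. The adjusted camera p values after correction were 9.07e-05, 0.000232, 0.00852 and 0.0223. They rest on the preset correlation of 0.01, so they carry little weight for lists whose genes correlate more. EV replicate 1 as the whole cause is argued against for ribosomal proteins, mitochondrially encoded transcripts and MAP kinase feedback. Without that library their mean differences went from 0.13 to 0.191, from -0.0651 to -0.0546 and from 0.118 to 0.119. Their adjusted camera p values, with the same preset correlation, were 2.26e-06, 0.00948 and 0.0253. For cholesterol synthesis the adjusted camera p without EV replicate 1 was 0.235, and the mean difference went from 0.15 to 0.08. There EV replicate 1 cannot be told apart from an effect of SCML4. Correlation of genes across libraries stays open for ribosomal proteins (estimate 0.607) and cholesterol synthesis (0.604); for mitochondrially encoded transcripts (-0.0638) and MAP kinase feedback (0.0197) the estimates were low, though 0 of the 35 lists were called with estimated correlations. An effect of SCML4 stays open for all 4, and cannot be told apart from any other difference between the EV and SCML4 cells.

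The 6 libraries can be divided 3 against 3 in 10 ways, too few for a share under 0.05. The number of genes changed by FPKM was 0 for the real groups and at most 0 for the others. A count of 0 is met by all 10 splits whatever the data, so that this count says nothing of the grouping. The weighted fit of reads gave 14 genes for the real groups and 35 at most for another split, and 2 of the 10 splits gave as many. That split set EV replicate 1 with SCML4 replicates 1 and 2, and gave 0 genes by FPKM. Camera gave 4 lists for the real groups and at most 6 for another split, and 6 of the 10 gave as many.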
